A study of Mus musculus with 10 samples.

How the data were processed

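The values are probe set intensities on a linear scale, as deposited by the submitters, 1 value per probe set and array, from 10 Affymetrix arrays hybridised with biotin-labelled cRNA, per the labels' protocols. How probe sets were summarised and how arrays were normalized is not given in the sources used here, and neither is a genome build, so no coordinates are printed. The table held 45037 probe sets, with no control probe sets among them, and all 10 columns matched a labelled sample. No negative or zero intensity was present, and log2 of the deposited intensity was taken with nothing added and with no further normalization. The median per array, 35.6 to 40.6 intensity units, stands in place of a sequencing depth, and the number of arrays limits the precision.

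Samples were grouped by the siRNA and time in their titles: siC and siLsd1 at 24 h, with 2 arrays each, and at 48 h, with 3 each. Per the labels' protocols, total RNA came from 3T3-L1 preadipocytes grown in DMEM with calf serum and transfected with 60 nM siRNA without a change of medium. The 24 h samples were of passage 19 and the 48 h samples of passage 21. Probe sets were named through the platform annotation, of which 34945 probe sets carried 1 gene symbol, 932 carried several and 9160 had no gene listed. Entrez identifiers of 34741 probe sets were found in the RefSeq table of GRCm38.p6, used for symbols alone, and 0 symbols changed. Where a gene had more than 1 probe set, as 9010 genes did, the probe set with the highest mean over all arrays stood for it, and other probe sets of a named gene are quoted where their sign differs. Among 223 called results of named genes with other probe sets, 57 of 398 other probe sets had the opposite sign, and 3 of these were called. Of 18193 genes, the 25% with the lowest mean over all arrays were left out as dim (4549 genes with a mean of up to 18.4 intensity units), and 13644 were tested.

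A linear model with a mean for each of the 4 groups was fitted to the 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), leaving 6 residual degrees of freedom, and 5 comparisons were taken from it. These were siLsd1 against siC at 24 h, at 48 h and for the mean of both times, the difference of the siLsd1 changes between the times, and siC at 48 h against siC at 24 h. The p-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Means ± SD are of linear intensities, while log2 changes and folds come from the log2 scale. The correlation of the changes at both times was computed across genes and carries no p-value.

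Gene lists numbering 32, covering LSD1 complexes, chromatin, adipogenesis, metabolism, the cell cycle, matrix, signalling, stress, immune response, markers of other cell types, ribosomal, lysosomal and RNA interference genes, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives, and members were counted over all genes tested and adjusted over the list alone.

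Named genes are Kdm1a, the 12 largest rises and 12 largest falls at 24 h and 48 h among called genes whose groups' arrays do not overlap, and up to 8 in each direction for the other comparisons, or the 5 with the smallest p where none was called. From each list up to 4 called members with the largest fold are named, or up to 2 with the smallest p as values, and Cebpa, Cebpb, Pparg, Dlk1, Wnt10b, Kdm1b, Rcor1 and Setdb1 whatever their values. Among the largest rises at 24 h, 1 uncharacterised symbol was passed over. The groups, tests, lists, naming rule and alternatives were set before the data were examined, apart from those named as chosen later.

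The fit was tested on simulated log2 values with 50 genes changed at each size among 13644. At 24 h it called 18, 64, 88 and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, at 48 h 30, 68, 94 and 100%, and for the mean of both times 46, 84, 94 and 100%. Of the unchanged genes, 0.0372%, 0.0223% and 0.0223% were called in these 3 comparisons. Of 100 simulated lists of 40 unchanged genes at 48 h, camera called 0. The simulated genes varied independently of one another, so this does not test calls of lists whose genes vary together.

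Alternatives were all probe sets, the mean of a gene's probe sets, no filter on dim genes, the lowest 50% left out, quantile normalization, arrays centred on the median, array weights, no intensity trend, a change of at least 1.5-fold, the arrays compared alone, an unequal-variance test per gene, a replicate block by number or by the sample code of the labels, and each array left out in turn. Chosen later were the intensity plus 16, intensities under 18.4 raised to that level, siLsd1 48 h replicates 1 and 2 averaged, and camera without an intensity trend. Probe sets without a single gene symbol were left out of the comparisons. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 in Python 3.11.15.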

Results

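Transcript levels were measured on 10 Affymetrix arrays in 3T3-L1 cells, a mouse fibroblast line whose cells are preadipocytes that can be induced to become fat cells. The cells had received either an siRNA against LSD1 (siLsd1), a histone demethylase encoded by Kdm1a, or a scrambled control siRNA (siC), each at 60 nM. RNA was collected at 24 h from cells of passage 19, with 2 arrays per siRNA, and at 48 h from cells of passage 21, with 3 arrays per siRNA. The labels call the replicates biological, and the p-values measure the spread between these samples. The median intensity per array lay between 35.6 and 40.6 (5.15 to 5.34 on the log2 scale), and single probe sets ranged from 0.76 to 15820.0. The number of arrays limits the precision of each comparison.

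Kdm1a, the targeted gene, was lower on each of the 5 siLsd1 arrays than on any siC array. By the brighter of its probe sets (Entrez gene 99982), the intensities at 24 h were 1559 and 1621 with siC against 1001 and 971 with siLsd1. At 48 h they were 1596, 1787 and 1775 with siC against 1352, 1336 and 897 with siLsd1. The group means fell from 1590.0 ± 43.2 to 986 ± 21.2 at 24 h (SD, n = 2), a 1.61-fold decrease (log2 change −0.69, SE 0.17, limma adjusted p 0.0473). At 48 h they fell from 1719 ± 107 to 1195 ± 258 (SD, n = 3), a 1.46-fold decrease (log2 change −0.55, SE 0.14, limma adjusted p 0.0338). The other probe set of the gene gave 604 and 569 against 327 and 332 at 24 h, and 656, 643 and 623 against 448, 449 and 338 at 48 h. The 48 h change was −0.35 without siLsd1 48 h replicate 3 (adjusted p 0.00277). The adjusted p at 24 h was 0.190, 0.218, 0.252 and 0.206 without siC 24 h replicate 1 or 2 or siLsd1 24 h replicate 1 or 2, and 0.0662, 0.0847 and 0.0776 without siC 48 h replicate 1, 2 or 3. At 48 h it was 0.0562 and 0.0563 without siC 24 h replicate 1 or 2, 0.0610 and 0.0611 without siLsd1 24 h replicate 1 or 2, and 0.0730, 0.115 and 0.0973 without siC 48 h replicate 1, 2 or 3. The 24 h call was also lost with all probe sets tested (adjusted p 0.0693), no filter on dim genes (0.0576), no intensity trend (0.0903) or a block by replicate number (0.107). The 48 h call was lost with no intensity trend (adjusted p 0.0649), the 48 h arrays fitted alone (0.104) or the block (0.0664).

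SiLsd1 48 h replicate 3 stood apart from its group. Over 6943 genes with a mean log2 intensity of at least 8, the SD of the log2 difference between arrays of the same group was 0.0892 to 0.205, whereas this array differed from its replicates by 0.441 and 0.439. Its SD from the siLsd1 24 h arrays was 0.361 and 0.353, and that of the other siLsd1 48 h arrays from them was 0.431 to 0.452. This array also had the lowest Kdm1a intensity of the 48 h arrays by both probe sets, at 897 and 338. The array enters the shared estimate of the spread in every comparison, and each leading count is therefore also given without it.

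**Figure D1:**
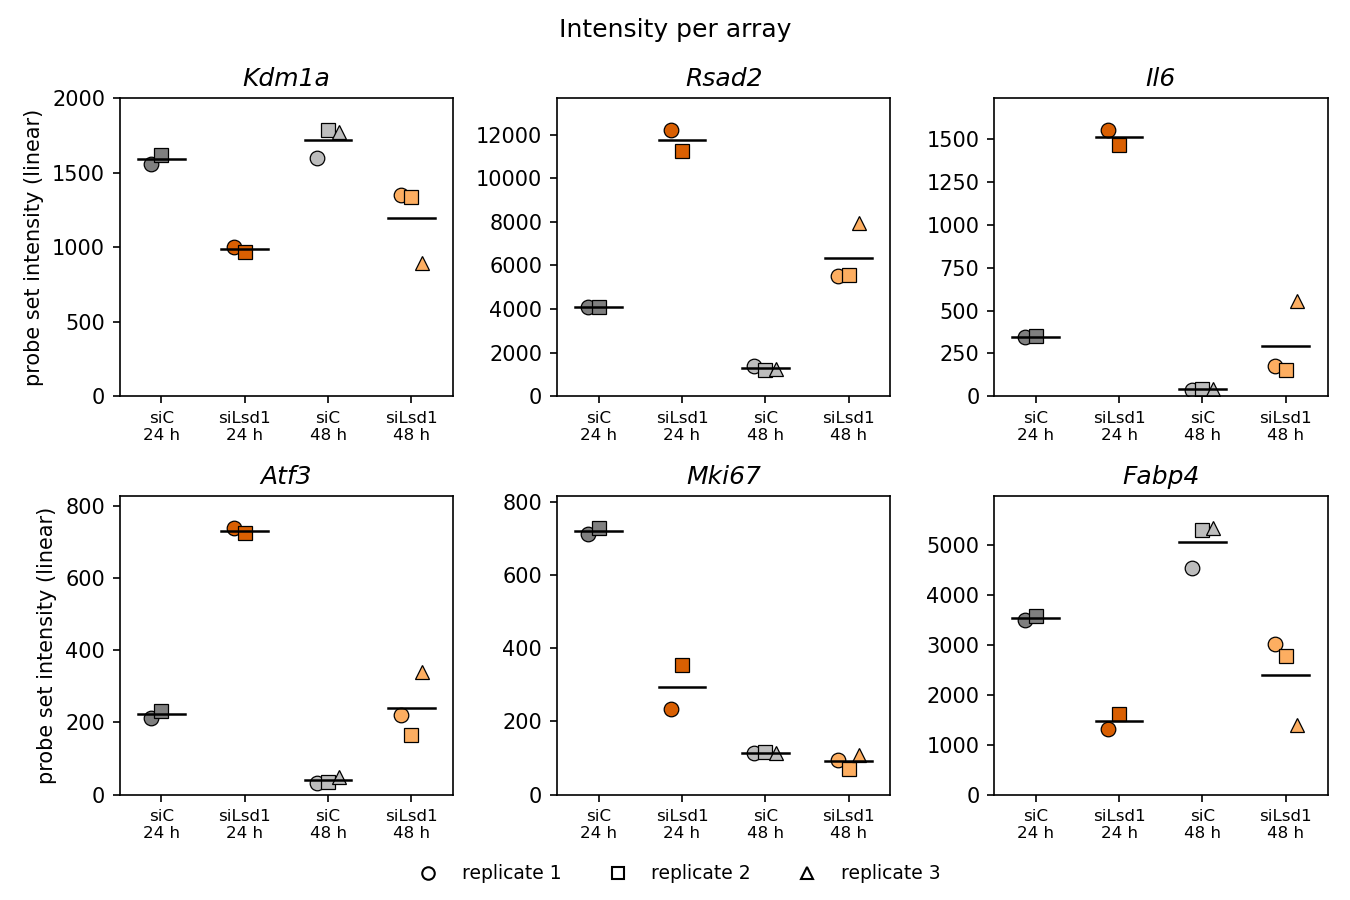
Intensity (linear scale) of Kdm1a, Rsad2, Il6, Atf3, Mki67 and Fabp4 on each of the 10 arrays, by group, with a marker shape per replicate number and a line at the group mean. The 5 siLsd1 arrays lie between 897 and 1352 for Kdm1a, below the siC arrays at 1559 to 1787.

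The comparison at 24 h asks which transcripts differed between cells with the siRNA against LSD1 and control cells at the earlier time. Of 40 interferon response genes 20 were called higher and 0 lower, and of 40 genes of G2 and mitosis 0 higher and 9 lower. Camera called both lists, neither was called with an estimated correlation (adjusted p = 0.10 and 0.596 with an estimated correlation), and fry called the interferon list alone of the 2. Ifnb1, which encodes interferon beta, rose 6.97-fold, from 99.9 ± 8.47 to 699 ± 106 intensity units (SD, n = 2; log2 change 2.80, SE 0.26, limma adjusted p 0.00153; Entrez gene 15977). Cxcl11, a chemokine gene induced by interferon, rose 5.34-fold, from 625 ± 0.431 to 3341 ± 306 (SD, n = 2; log2 change 2.42, SE 0.28, limma adjusted p 0.00307). Map2k6, which encodes a kinase upstream of p38, fell 4.18-fold, from 276 ± 14.0 to 65.9 ± 2.47 (SD, n = 2; log2 change −2.06, SE 0.24, limma adjusted p 0.00307).

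A floored fold has intensities under 18.4, the level below which genes were left out as dim, raised to that level. Ifna4 rose 12.9-fold, and Ifna2 and Ifna5 rose a floored 13.1- and 6.60-fold, but interferon alpha genes are near-identical in sequence, so the assignment of this signal to single members is uncertain. Among the other largest rises, the chemokine gene Ccl4 rose a floored 7.33-fold and Ccl5 rose 4.82-fold. The cytokine gene Il6 rose 4.33-fold from 348 ± 4.85 to 1509 ± 61.5 (SD, n = 2; log2 change 2.12, SE 0.47, limma adjusted p 0.0330). Ifit1bl1, Ctss, Ccrl2 and Ifi209 rose 4.96-, 4.5-, 4.44- and 4.36-fold. Among the largest falls, Cenpf and Kif11 fell 3.49- and 2.72-fold, genes of a kinetochore protein and a spindle motor. The Cenpf mean went from 207 ± 4.96 to 60.1 ± 14.3 (SD, n = 2; log2 change −1.80, SE 0.28, limma adjusted p 0.00806). E2f8 and Timeless fell 3.05- and 2.74-fold, the latter a component of the replication fork. Hip1, Gas7, Zfp354c, Itgbl1 and Bbip1 fell 3.03-, 2.97-, 2.84-, 2.73- and 2.72-fold (log2 change of other probe sets of Hip1 at 0.05 and 0.20). The calls of Fgf13 and Gpr37l1 were lost with low intensities raised (adjusted p 0.278 and 0.306).

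limma called 736 of 13644 genes at 24 h, 355 higher and 381 lower with siLsd1, and 159 of them changed more than 2-fold (73 higher and 86 lower). With each array centred on its median the count was 870, split into 330 higher and 540 lower. Without siLsd1 48 h replicate 3, which is in neither group compared, it was 3478 (1384 higher and 2094 lower). It was 43 and 64 without siC 24 h replicate 1 or 2, 30 and 131 without siLsd1 24 h replicate 1 or 2, and 357 and 466 without siC 48 h replicate 2 or 3. Of the 88 called genes named at 24 h, the calls of 11 held with each array left out in turn, namely Ccl4, Ccl8, Ccrl2, Gadd45g, Ifit2, Ifna4, Ifna5, Ifnb1, Map2k6, Mmp9 and Rsad2. Among the 88, 74 and 72 lost the call without siC 24 h replicate 1 or 2, 77 and 60 without siLsd1 24 h replicate 1 or 2, 23, 34 and 24 without siC 48 h replicate 1, 2 or 3, and 8 and 6 without siLsd1 48 h replicate 1 or 2.

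Of the 40 interferon response genes tested, 20 rose and 0 fell (25 and 1 adjusted over the list alone). The interferon list had a median log2 change of 0.41 (camera adjusted p 5.22e-19, and adjusted p = 0.10 with an estimated correlation). Oasl1, Rsad2, Ifit2 and Mx1 rose 3.80-, 2.87-, 2.83- and 2.03-fold, of which Rsad2, Ifit2 and Mx1 encode antiviral effectors. With siLsd1 48 h replicate 3 left out, 29 rose and 1 fell. Of the 32 inflammatory cytokine and NF-kB target genes tested, 14 rose and 0 fell (17 and 0 adjusted over the list alone). The inflammatory list had a median log2 change of 0.60 (camera adjusted p 8.95e-14, and adjusted p = 0.10 with an estimated correlation). Among them, Ccl8 and Tslp rose 3.85- and 3.13-fold, a chemokine and a cytokine gene. Of the 26 p53 target and cell cycle arrest genes tested, 5 rose and 1 fell (7 and 1 adjusted over the list alone). The p53 list had a median log2 change of 0.16 (camera adjusted p 0.00742, and adjusted p = 0.118 with an estimated correlation). Gadd45b, Gadd45g and Fas rose 2.37-, 2.24- and 1.49-fold, and Cdkn2c fell 1.92-fold. Of the 34 oxidative stress and NRF2 target genes tested, 2 rose and 1 fell (11 and 3 adjusted over the list alone). The NRF2 list had a median log2 change of 0.16 (camera adjusted p 0.00923, and adjusted p = 0.10 with an estimated correlation). Hmox1 and Srxn1 rose 2.44- and 2.26-fold (log2 change of another probe set of Srxn1 at −0.03), and Gstm5 fell 1.55-fold; the rises encode heme oxygenase and sulfiredoxin. Of the 41 growth factor and immediate early genes tested, 5 rose and 1 fell (7 and 4 adjusted over the list alone). The growth factor list had a median log2 change of 0.23 (camera adjusted p 0.0171, and adjusted p = 0.365 with an estimated correlation). Dusp4, Dusp1 and Ier3 rose 2.70-, 2.40- and 1.94-fold, the Dusp genes encoding phosphatases of MAP kinases, and Etv5 fell 1.76-fold.

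Of the 40 genes of G2 and mitosis tested, 0 rose and 9 fell (0 and 23 adjusted over the list alone). The G2 and mitosis list had a median log2 change of −0.80 (camera adjusted p 1.50e-13, and adjusted p = 0.596 with an estimated correlation). The proliferation marker Mki67 fell 2.51-fold from 721 ± 11.8 to 294 ± 84.6 (SD, n = 2; log2 change −1.33, SE 0.22, limma adjusted p 0.00995), and Prc1 fell 2.38-fold. With siLsd1 48 h replicate 3 left out, 0 rose and 34 fell. Of the 38 genes of S phase and replication tested, 0 rose and 3 fell (0 and 5 adjusted over the list alone). The S phase list had a median log2 change of −0.28 (camera adjusted p 0.000128, and adjusted p = 0.890 with an estimated correlation). Pola1, Lig1 and Pold1 fell 1.60-, 1.51- and 1.44-fold (log2 change of 0.30 for the mean over the probe sets of Pola1). Of the 34 mature adipocyte markers tested, 0 rose and 4 fell (0 and 11 adjusted over the list alone). The mature adipocyte list had a median log2 change of −0.17 (camera adjusted p 0.0103, and adjusted p = 0.10 with an estimated correlation). Fabp4, Cd36, Cd24a and Fabp5 fell 2.42-, 2.00-, 1.94- and 1.38-fold (log2 change of another probe set of Fabp4 at 0.19), the Fabp genes encoding fatty acid binding proteins and Cd36 a fatty acid transporter. Of the 53 extracellular matrix genes tested, 2 rose and 4 fell (3 and 6 adjusted over the list alone). The matrix list had a median log2 change of −0.26 (camera adjusted p 0.0237, and adjusted p = 0.930 with an estimated correlation). Mmp9 and Col6a2 fell 2.11- and 1.54-fold, while Has2 and Ccn1 rose 1.95- and 1.57-fold. With camera run without an intensity trend, the call of the matrix list was lost (camera adjusted p 0.05002). With the mean of a gene's probe sets, the call of the growth factor list was lost (camera adjusted p 0.0627) and that of the mature adipocyte list (0.0825). With quantile normalization, the call of the NRF2 list was lost (camera adjusted p 0.0577), and the oxidative phosphorylation and LSD1 complex lists were called lower (0.00764 and 0.0487). Fry did not call the lists of G2 and mitosis (adjusted p 0.0998), S phase (0.286), matrix (0.534) or growth factors (0.141), and it called the RNA interference list (0.0310). The matrix call was lost at camera adjusted p of 0.0894 without siC 24 h replicate 1 and 0.0604 without siLsd1 24 h replicate 2. Camera also called, with 1 array left out, the LSD1 complex list (adjusted p 0.0465 without siLsd1 48 h replicate 3), cholesterol list (adjusted p 0.0334 without siLsd1 24 h replicate 2 and 0.0373 without siLsd1 48 h replicate 3) and oxidative phosphorylation list (adjusted p 0.0267 without siC 24 h replicate 2).

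The comparison at 48 h asks the same question a day later, in cells of a later passage. Of 40 interferon response genes 26 were called higher and 1 lower, and of 53 matrix genes 4 higher and 10 lower. Camera called both lists, neither was called with an estimated correlation (adjusted p = 0.0692 and 0.935 with an estimated correlation), and fry called the interferon list alone of the 2. Rsad2, an antiviral effector, rose 4.88-fold, from 1283 ± 98.4 to 6349.9 ± 1395 intensity units (SD, n = 3; log2 change 2.29, SE 0.13, limma adjusted p 3.99e-05; Entrez gene 58185). Atf3, a stress-induced transcription factor, rose 6.02-fold, from 39.0 ± 9.28 to 241 ± 89.0 (SD, n = 3; log2 change 2.59, SE 0.24, limma adjusted p 0.000315). Adamts12, a secreted metalloprotease, fell 4.85-fold, from 979 ± 28.9 to 254 ± 159.9 (SD, n = 3; log2 change −2.28, SE 0.50, limma adjusted p 0.0219). Without siLsd1 48 h replicate 3 the fall of Adamts12 was 2.83-fold (adjusted p 2.38e-06).

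Among the largest rises, Cxcl11, Cxcl9 and Cxcl10 rose 8.46-, 6.26- and 5.06-fold, all interferon-induced chemokine genes. The Cxcl10 mean went from 663 ± 129 to 3332 ± 487 (SD, n = 3; log2 change 2.34, SE 0.14, limma adjusted p 5.33e-05). Il6 rose 6.17-fold from 40.05 ± 3.46 to 295 ± 228 (SD, n = 3; log2 change 2.62, SE 0.39, limma adjusted p 0.00473), and 4.10-fold without siLsd1 48 h replicate 3. Serpinb9g rose a floored 4.72-fold and Serpinb2 5.32-fold, both of them protease inhibitor genes, and the acute phase gene Saa3 rose 5.19-fold. Mpeg1 rose 5.67-fold, and Ifi209 and Ifna4 rose a floored 5.45- and 3.90-fold. Among the largest falls, Lum and Mgp fell 3.36- and 3.27-fold and Dmp1 a floored 1.98-fold, genes of the matrix proteins lumican, matrix Gla protein and a matrix phosphoprotein. The Mgp mean went from 758 ± 92.5 to 256.01 ± 122 (SD, n = 3; log2 change −1.71, SE 0.33, limma adjusted p 0.0147). Epas1, Mertk and Agt fell 2.95-, 3.15- and 3.03-fold; they encode a hypoxia-inducible transcription factor, a receptor kinase and angiotensinogen. Sycp2, Sult1a1, Sned1, Tbx6 and Nol4l fell 4.28-, 3.44-, 3.30-, 3.02- and 2.87-fold. Without siLsd1 48 h replicate 3, Saa3 rose 2.76-fold, Sycp2, Sned1 and Agt fell 2.44-, 2.05- and 1.96-fold, and the log2 change of Serpinb9g went from 2.62 to 1.77; without replicate 2, Saa3 rose 8.04-fold.

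limma called 1728 of 13644 genes at 48 h, 818 higher and 910 lower with siLsd1, and 195 of them changed more than 2-fold (126 higher and 69 lower). With each array centred on its median the count was 1799, split into 1043 higher and 756 lower. Without siLsd1 48 h replicate 3 it was 2473 (1114 higher and 1359 lower), and 1666 of the 1728 genes were among them in the same direction. It was 1020 and 1013 without siC 24 h replicate 1 or 2, 876 and 878 without siLsd1 24 h replicate 1 or 2, and 489, 382 and 560 without siC 48 h replicate 1, 2 or 3. Of the 100 called genes named at 48 h, the calls of 33 held with each array left out in turn, among them Rsad2, Atf3, Cxcl9, Cxcl10, Cxcl11, Il6, Lum and Epas1. Among the 100, 38 lost the call without either siC 24 h array, 41 and 40 without siLsd1 24 h replicate 1 or 2, 61, 62 and 60 without siC 48 h replicate 1, 2 or 3, and 7, 6 and 3 without siLsd1 48 h replicate 1, 2 or 3.

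Of the 40 interferon response genes tested, 26 rose and 1 fell (28 and 1 adjusted over the list alone). The interferon list had a median log2 change of 0.56 (camera adjusted p 1.30e-23, and adjusted p = 0.0692 with an estimated correlation). Mx1 rose 4.16-fold and Oasl1 a floored 1.85-fold, and the list median lay at 0.58, 0.63 and 0.46 on siLsd1 48 h replicates 1, 2 and 3, against 0.47 and 0.33 on the siLsd1 24 h arrays. With replicate 3 of siLsd1 left out, 35 rose and 1 fell. Of the 32 inflammatory cytokine and NF-kB target genes tested, 15 rose and 0 fell (16 and 2 adjusted over the list alone). The inflammatory list had a median log2 change of 0.39 (camera adjusted p 1.40e-06, and adjusted p = 0.541 with an estimated correlation). Ptgs2 and Il13ra1 rose 2.38- and 2.23-fold, and the list median was 0.67 on siLsd1 48 h replicate 3 against 0.35 and 0.26 on its replicates. Of the 41 ER stress and ATF4 target genes tested, 17 rose and 5 fell (21 and 11 adjusted over the list alone). The ER stress list had a median log2 change of 0.44 (camera adjusted p 0.000240, and adjusted p = 0.567 with an estimated correlation). Chac1, Slc7a5 and Wars rose 2.57-, 2.20- and 2.18-fold; Chac1 is an ATF4 target, and Slc7a5 and Wars encode an amino acid transporter and a tRNA synthetase. The list median was 0.68 on siLsd1 48 h replicate 3 against 0.34 and 0.24 on its replicates, and without replicate 3, 20 rose and 5 fell.

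Of the 53 extracellular matrix genes tested, 4 rose and 10 fell (5 and 20 adjusted over the list alone). The matrix list had a median log2 change of −0.28 (camera adjusted p 0.000240, and adjusted p = 0.935 with an estimated correlation). Col8a1 fell 2.51-fold, while the collagenase gene Mmp13 rose 3.84-fold. The list median was −0.58 on siLsd1 48 h replicate 3 against −0.13 and −0.12 on its replicates, and without replicate 3, 4 rose and 18 fell, with a median of −0.13 (camera adjusted p 0.000340). Of the 40 genes of G2 and mitosis tested, 2 rose and 0 fell (2 and 0 adjusted over the list alone). The G2 and mitosis list had a median log2 change of 0.25 (camera adjusted p 0.0108, and adjusted p = 0.946 with an estimated correlation). Ccnf and Tpx2 rose 2.22- and 1.45-fold. The list median was 0.74 on siLsd1 48 h replicate 3 against 0.05 and −0.09 on its replicates, and without replicate 3 the median was −0.03 and the call was lost (camera adjusted p 0.908). With the mean of a gene's probe sets, the call of the G2 and mitosis list was lost (camera adjusted p 0.115). Fry did not call the matrix list (adjusted p 0.228) or that of G2 and mitosis (0.625), and it called the mature adipocyte (0.0265) and NRF2 lists (0.0195). Camera also called, with 1 array left out, the S phase list (adjusted p 0.0239 without siLsd1 48 h replicate 2), cholesterol list (adjusted p 0.00359 without siLsd1 48 h replicate 3), oxidative phosphorylation list (adjusted p 0.0276 without siLsd1 48 h replicate 3), NRF2 list (adjusted p 0.0162 without siLsd1 48 h replicate 3) and pro-adipogenic list (adjusted p 0.0122 without siLsd1 48 h replicate 1 and 0.0271 without siLsd1 48 h replicate 2).

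Of the 9 lists called at 24 h, 5 missed the threshold at 48 h, which does not show that the times differ. Of the 34 mature adipocyte markers at 48 h, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with a camera adjusted p of 0.295. Fabp4, Elovl6, Plin4 and Fabp5 fell 2.23-, 1.89-, 1.5- and 1.2-fold. Of the 34 oxidative stress and NRF2 target genes, 9 rose and 3 fell (12 and 5 adjusted over the list alone), with a camera adjusted p of 0.138. Gsta3, Hmox1 and Gsta2 rose 2.61-, 2.51- and 2.29-fold, while Aldh3a1 fell 2.26-fold. Of the 26 p53 target and arrest genes, 6 rose and 2 fell (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.295. Gadd45a, Plk2 and Gadd45b rose 2.32-, 1.80- and 1.69-fold, while Cdkn2c fell 1.62-fold. Of the 41 growth factor and immediate early genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.879. Ereg rose 1.94-fold and Egr3 fell 1.94-fold (log2 change of another probe set of Egr3 at 0.15). Among 38 S phase genes limma called 0 (8 at an unadjusted p under 0.05, and 0 adjusted over the list alone), with log2 changes of 0.55 for Mcm3 (adjusted p 0.0623) and 0.40 for Rfc3 (adjusted p 0.0786) and a camera adjusted p of 0.295. Conversely, the ER stress and ATF4 list, called at 48 h, missed the threshold at 24 h (camera adjusted p 0.462). At that time 1 rose and 3 fell (1 and 3 adjusted over the list alone). Atf3 rose 3.29-fold, and Atf6, Pdia4 and Herpud1 fell 1.75-, 1.51- and 1.33-fold (log2 change of another probe set of Atf6 at 0.41).

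**Figure D2:**
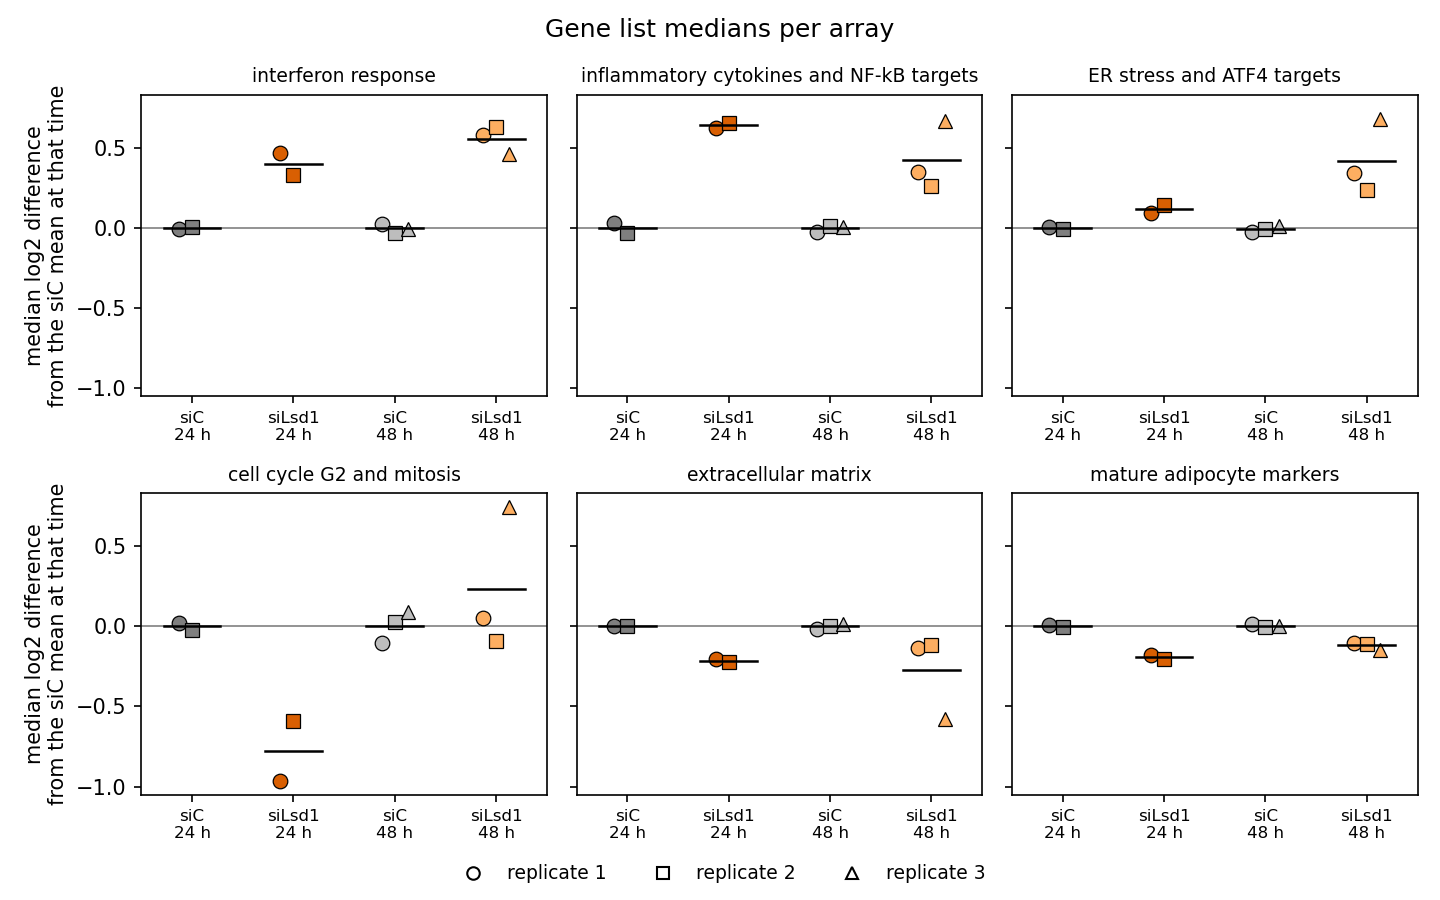
Median log2 difference of 6 gene lists from the siC mean of the same time, for each array (points, with a marker shape per replicate number) and each group (lines at the mean). The interferon list lies between 0.33 and 0.63 on the 5 siLsd1 arrays, and the list of G2 and mitosis genes lies at 0.74 on siLsd1 48 h replicate 3 and at 0.05 and −0.09 on its replicates.

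Adipogenesis regulators and partners of LSD1 were measured at both times. Cebpb, an early adipogenic transcription factor gene, rose 1.39-fold at 48 h (log2 change 0.47, SE 0.11, limma adjusted p 0.0263), and its log2 change at 24 h was 0.42 (adjusted p 0.102). The log2 changes at 24 h were −0.45 for Cebpa (adjusted p 0.282), −0.05 for Pparg (adjusted p 0.764) and −0.32 for Dlk1 (adjusted p 0.0653). At 48 h they were −0.64 for Cebpa (adjusted p 0.0506), −0.20 for Pparg (adjusted p 0.0692) and −0.20 for Dlk1 (adjusted p 0.0945). Kdm1b, the other LSD1-type demethylase gene, Rcor1, a partner of LSD1, and Setdb1 had log2 changes of −0.06, −0.07 and 0.05 at 24 h and 0.21, 0.21 and −0.04 at 48 h, and none was called. Wnt10b lay among the dim genes left out of the tests.

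The remaining lists were called by camera at neither time. Of 28 genes of LSD1 complexes, 1 rose and 2 fell at 24 h, and 1 rose and 3 fell at 48 h. The LSD1 complex list held 2 higher and 3 lower at 24 h and 2 and 3 at 48 h adjusted over the list alone, with camera adjusted p of 0.0994 and 0.879. Chd4 fell 1.46-fold (log2 change of another probe set of Chd4 at 0.04) and Mbd2 rose 1.25-fold at 24 h, while at 48 h Rreb1 and Gatad2b fell 1.37- and 1.26-fold (log2 change of other probe sets of Rreb1 at 0.09 and 0.26 and other probe sets of Gatad2b at 0.09 and 0.11) and Gatad2a rose 1.31-fold (log2 change of another probe set of Gatad2a at −0.07). Of 44 histone methylation enzyme genes, 2 rose and 2 fell at 24 h, and 2 rose and 5 fell at 48 h. The histone methylation list held 2 higher and 4 lower at 24 h and 4 and 7 at 48 h adjusted over the list alone, with camera adjusted p of 0.484 and 0.877. Setdb2 rose 1.56-fold at 24 h and 2.26-fold at 48 h, while Nsd1 and Smyd2 fell 1.79- and 1.40-fold at 24 h and 1.71- and 1.42-fold at 48 h. Of 36 pro-adipogenic regulators, 1 rose and 1 fell at 24 h, and 1 rose and 3 fell at 48 h. The pro-adipogenic list held 1 higher and 1 lower at 24 h and 1 and 6 at 48 h adjusted over the list alone, with camera adjusted p of 0.294 and 0.0624. At 48 h camera called it lower with quantile normalization (0.0312) and with no filter on dim genes (0.0483). At 48 h, Igf1, Fto and Nr3c1 fell 2.15-, 1.41- and 1.29-fold (log2 change of another probe set of Fto at 0.81 and other probe sets of Nr3c1 at 0.20 and 0.04). Of 41 anti-adipogenic regulators, 1 rose and 0 fell at 24 h, and 2 rose and 4 fell at 48 h. The anti-adipogenic list held 1 higher and 0 lower at 24 h and 2 and 4 at 48 h adjusted over the list alone, with camera adjusted p of 0.951 and 0.429. At 48 h, Vdr and Foxo1 fell 1.55- and 1.36-fold, and Ddit3 and Inhba rose 1.41- and 1.37-fold (log2 change of another probe set of Ddit3 at −0.71 and another probe set of Inhba at −0.12). Of 34 regulators of oxidative energy metabolism, 1 rose and 1 fell at 24 h, and 3 rose and 1 fell at 48 h. The oxidative metabolism list held 1 higher and 1 lower at 24 h and 4 and 3 at 48 h adjusted over the list alone, with camera adjusted p of 0.404 and 0.891. Tfam rose 1.45-fold at 24 h and 1.53-fold at 48 h, and Acadm fell 1.76-fold at 24 h and 1.57-fold at 48 h; Tfam maintains mitochondrial DNA and Acadm acts in fatty acid oxidation. Of 63 oxidative phosphorylation subunit genes, limma called 0 at 24 h (13 at an unadjusted p under 0.05), and 1 rose and 3 fell at 48 h. The oxidative phosphorylation list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.294 and 0.343. With quantile normalization camera called it lower at both times (0.00764 and 0.0174). Of 23 genes of glycolysis and glucose uptake, 0 rose and 2 fell at 24 h, and 5 rose and 3 fell at 48 h. The glycolysis list held 0 higher and 3 lower at 24 h and 6 and 3 at 48 h adjusted over the list alone, with camera adjusted p of 0.738 and 0.138. At 48 h, Hk2 and Pfkfb3 rose 2.13- and 1.85-fold, both acting early in glycolysis, and Pfkm fell 1.72-fold. Of 20 cholesterol biosynthesis genes, limma called 0 at 24 h (2 at an unadjusted p under 0.05), and 1 rose and 0 fell at 48 h. The cholesterol list held 0 higher and 0 lower at 24 h and 1 and 2 at 48 h adjusted over the list alone, with camera adjusted p of 0.114 and 0.891. At 48 h, Sc5d rose 1.55-fold (log2 change of another probe set of Sc5d at −0.21).

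Of 24 contractile and smooth muscle genes, 3 rose and 1 fell at 24 h, and 4 rose and 1 fell at 48 h. The contractile list held 3 higher and 2 lower at 24 h and 5 and 1 at 48 h adjusted over the list alone, with camera adjusted p of 0.404 and 0.457. At 48 h, Tagln2, Actg2, Des and Acta2 rose 1.57-, 1.56-, 1.42- and 1.25-fold (log2 change of another probe set of Acta2 at −0.75), and the mean over the probe sets of Des changed by −0.21. Of 35 Wnt signalling genes, 1 rose and 2 fell at 24 h, and 1 rose and 0 fell at 48 h. The Wnt list held 1 higher and 2 lower at 24 h and 0 and 0 at 48 h adjusted over the list alone, with camera adjusted p of 0.951 and 0.877. Ccn4 rose 1.91-fold at 24 h and Myc rose 2.08-fold at 48 h. Of 39 TGF-beta and BMP signalling genes, 2 rose and 1 fell at 24 h, and 4 rose and 3 fell at 48 h. The TGF-beta and BMP list held 2 higher and 1 lower at 24 h and 5 and 5 at 48 h adjusted over the list alone, with camera adjusted p of 0.951 and 0.879. Bambi rose 2.10-fold at 24 h, and Bmp1 and Ltbp2 fell 1.80- and 1.52-fold and Smad2 and Tgif1 rose 1.44- and 1.42-fold (log2 change of another probe set of Smad2 at −0.40, adjusted p 0.0440) at 48 h. Of 22 Notch signalling genes, limma called 0 at 24 h (0 at an unadjusted p under 0.05), and 1 rose and 1 fell at 48 h. The Notch list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.951 and 0.942. Of 23 Hox genes, limma called 0 at 24 h (4 at an unadjusted p under 0.05), and 1 rose and 1 fell at 48 h. The Hox list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.951 and 0.463. Of 23 neuronal genes, 0 rose and 1 fell at 24 h, and 0 rose and 1 fell at 48 h. The neuronal list held 0 higher and 1 lower at 24 h and 0 and 1 at 48 h adjusted over the list alone, with camera adjusted p of 0.738 and 0.879. Ncam1 fell 1.77-fold (log2 change of other probe sets of Ncam1 at 0.04 and 0.03) at 24 h, and Ncam1 fell 1.57-fold (log2 change of other probe sets of Ncam1 at 0.00 and 0.37) at 48 h. Of 14 germline genes, 1 rose and 0 fell at 24 h, and 1 rose and 1 fell at 48 h. The germline list held 1 higher and 0 lower at 24 h and 1 and 1 at 48 h adjusted over the list alone, with camera adjusted p of 0.951 and 0.879. Usp17la rose 1.71-fold at 24 h and 2.20-fold at 48 h. Of 19 bone and cartilage markers, 0 rose and 1 fell at 24 h, and 0 rose and 2 fell at 48 h. The bone list held 0 higher and 1 lower at 24 h and 0 and 2 at 48 h adjusted over the list alone, with camera adjusted p of 0.951 and 0.649. Of 19 skeletal muscle markers, limma called 0 at 24 h (3 at an unadjusted p under 0.05), and 1 rose and 1 fell at 48 h. The skeletal muscle list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.294 and 0.942. Of 9 endothelial markers, limma called 0 at 24 h and 0 at 48 h (0 and 1 at an unadjusted p under 0.05). The endothelial list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.653 and 0.443. Of 15 macrophage and leukocyte markers, limma called 0 at 24 h and 0 at 48 h (0 and 0 at an unadjusted p under 0.05). The leukocyte list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.951 and 0.973. Among the latter, the log2 changes at 24 h were 0.27 for Cd14 (adjusted p 0.244) and −0.55 for Cd52 (adjusted p 0.293). Of 41 ribosomal protein genes, limma called 0 at 24 h and 0 at 48 h (3 and 1 at an unadjusted p under 0.05). The ribosomal list held 0 at either time adjusted over the list alone, with camera adjusted p of 0.294 and 0.879. Of 40 lysosome and autophagy genes, 6 rose and 2 fell at 24 h, and 4 rose and 5 fell at 48 h. The lysosome list held 8 higher and 4 lower at 24 h and 4 and 6 at 48 h adjusted over the list alone, with camera adjusted p of 0.404 and 0.942. Gla rose 2.05-fold at 24 h and 2.12-fold at 48 h, and Ctss rose 2.59-fold while Ctsf and Gusb fell 1.80- and 1.5-fold at 48 h. Of 15 genes of the RNA interference machinery, 0 rose and 1 fell at 24 h, and 0 rose and 2 fell at 48 h. The RNA interference list held 1 higher and 7 lower at 24 h and 1 and 3 at 48 h adjusted over the list alone, with camera adjusted p of 0.114 and 0.295. Prkra fell 1.80-fold at 24 h and 1.48-fold at 48 h.

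The calls at the 2 times overlapped; the comparisons share no arrays, but they share each gene's estimate of the spread and so are not independent. Of the genes called higher, 250 were called higher at both times, where 21.3 would be shared by independent lists of these sizes. Of those called lower, 224 were shared, where 25.4 would be; 0 were called in opposite directions. In separate fits of each time, which share neither arrays nor that estimate, 152 of the 175 genes called higher at 48 h were called higher at 24 h, where 16.5 would be shared by independent lists. Of the 75 lower, 61 were shared, where 10.4 would be, and 0 were called in opposite directions. Of the 355 genes higher at 24 h, 338 had a change of the same sign at 48 h, and so had 361 of the 381 genes lower. Across the 13644 genes, which are not independent replicates, the log2 changes at 24 h and 48 h correlated with a Pearson r of 0.617 (Spearman rho 0.588), and with 0.560 (rho 0.547) without siLsd1 48 h replicate 3.

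**Figure D3:**
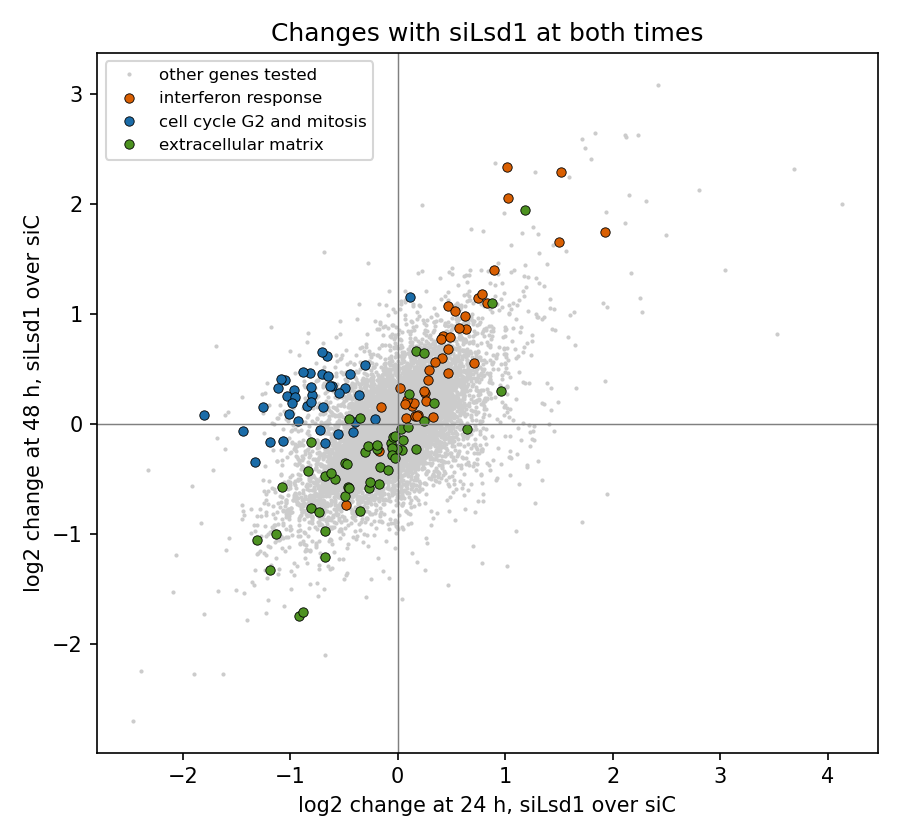
Log2 change with siLsd1 at 48 h (vertical axis) against the change at 24 h (horizontal axis) for each of 13644 genes, in grey, with genes of the interferon response in orange, of G2 and mitosis in blue and of the extracellular matrix in green. The Pearson correlation across genes is 0.617.

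The mean of both times asks how siLsd1 and siC differed on average over 24 h and 48 h, which does not show that a change is shared by both times. Ifna2 rose a floored 4.49-fold (log2 change as measured 3.07, SE 0.30, limma adjusted p 0.000241; n = 5 arrays per siRNA), and Il6 rose 5.17-fold (log2 change 2.37, SE 0.31, limma adjusted p 0.00103). Cxcl11, Ifnb1 and Cxcl9 rose 6.72-, 5.52- and 4.73-fold, and Ifna4, Ifi209 and Serpinb9g rose a floored 7.10-, 4.87- and 4.72-fold. Col27a1, a fibrillar collagen gene, fell a floored 5.67-fold (log2 change as measured −2.58, SE 0.69, limma adjusted p 0.0242, and −1.90 without siLsd1 48 h replicate 3). Lrrc17, Adamts12, Sparcl1, Sned1, Map2k6 and Nol4l fell 4.99-, 4.25-, 3.87-, 3.40-, 3.09- and 3.02-fold and Tmem44 a floored 2.35-fold; without that array Lrrc17 fell 3.22-fold. Kdm1a fell 1.54-fold (log2 change −0.62, SE 0.11, limma adjusted p 0.00481). Cebpa fell 1.46-fold and Dlk1 fell 1.2-fold, while Cebpb rose 1.36-fold; Pparg had a log2 change of −0.13 (adjusted p 0.108).

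limma called 3250 of 13644 genes for the mean of both times, 1384 higher and 1866 lower, and 4617 (1979 higher and 2638 lower) without siLsd1 48 h replicate 3. The count was 1629 and 1762 without siC 24 h replicate 1 or 2, 1346 and 1628 without siLsd1 24 h replicate 1 or 2, and 2142 without siC 48 h replicate 2. Of the 129 called genes named here, the calls of 70 held with each array left out, Kdm1a, Il6, Ifnb1, Mgp, Fabp4 and Mki67 among them. Among the 129, 53 and 43 lost the call without siC 24 h replicate 1 or 2, 54 and 48 without siLsd1 24 h replicate 1 or 2, 23, 25 and 25 without siC 48 h replicate 1, 2 or 3, and 6 and 5 without siLsd1 48 h replicate 1 or 2. Of the 40 interferon response genes tested, 27 rose and 1 fell (31 and 1 adjusted over the list alone). The interferon list had a median log2 change of 0.49 (camera adjusted p 1.43e-21, and adjusted p = 0.0868 with an estimated correlation). Of the 32 inflammatory cytokine and NF-kB target genes tested, 19 rose and 0 fell (20 and 1 adjusted over the list alone). The inflammatory list had a median log2 change of 0.59 (camera adjusted p 2.19e-10, and adjusted p = 0.192 with an estimated correlation). Ccl5 and Saa3 rose 3.12- and 3.12-fold and Ccl20 a floored 2.95-fold. Of the 41 ER stress and ATF4 target genes tested, 17 rose and 8 fell (19 and 10 adjusted over the list alone). The ER stress list had a median log2 change of 0.24 (camera adjusted p 0.0161, and adjusted p = 0.767 with an estimated correlation). Atf3, Chac1 and Ppp1r15a rose 4.45-, 1.91- and 1.72-fold. Of the 34 NRF2 target genes tested, 12 rose and 3 fell (12 and 4 adjusted over the list alone). The NRF2 list had a median log2 change of 0.06 (camera adjusted p 0.0335, and adjusted p = 0.192 with an estimated correlation). Of the 26 p53 target genes tested, 11 rose and 3 fell (12 and 4 adjusted over the list alone). The p53 list had a median log2 change of 0.17 (camera adjusted p 0.0354, and adjusted p = 0.251 with an estimated correlation). Gadd45b rose 2.00-fold and Sesn1 fell 2.16-fold (log2 change of another probe set of Sesn1 at 0.23). Of the 53 matrix genes tested, 5 rose and 19 fell (7 and 23 adjusted over the list alone). The matrix list had a median log2 change of −0.25 (camera adjusted p 0.00203, and adjusted p = 0.893 with an estimated correlation). Lum, Mgp and Col8a1 fell 2.52-, 2.46- and 2.39-fold, and Mmp13 rose 2.95-fold. Of the 34 mature adipocyte markers tested, 2 rose and 10 fell (2 and 10 adjusted over the list alone). The mature adipocyte list had a median log2 change of −0.18 (camera adjusted p 0.0369, and adjusted p = 0.192 with an estimated correlation). Fabp4, Elovl6, Cd36 and Acacb fell 2.33-, 1.99-, 1.55- and 1.49-fold (log2 change of another probe set of Elovl6 at 0.08 and another probe set of Acacb at 0.08). Of the 40 genes of G2 and mitosis tested, 0 rose and 4 fell (0 and 3 adjusted over the list alone). The G2 and mitosis list had a median log2 change of −0.29 (camera adjusted p 0.00599, and adjusted p = 0.893 with an estimated correlation), from −0.80 at 24 h and 0.25 at 48 h. Cenpf, Mki67 and Kif11 fell 1.82-, 1.78- and 1.69-fold (log2 change of another probe set of Cenpf at 0.19).

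Calls of lists for the mean of both times were lost when 1 array was left out. These were G2 and mitosis at a camera adjusted p of 0.0575 without siLsd1 24 h replicate 1 and 0.0507 without siLsd1 48 h replicate 2. The mature adipocyte call was lost at 0.0948 without siC 48 h replicate 1, 0.0551 without siLsd1 24 h replicate 1, 0.0615 without siLsd1 48 h replicate 1 and 0.0507 without siLsd1 48 h replicate 2. The p53 call was lost at 0.0564 without siC 48 h replicate 1, 0.0551 without siLsd1 24 h replicate 1, 0.0615 without siLsd1 48 h replicate 1 and 0.0507 without siLsd1 48 h replicate 2. With camera run without an intensity trend, the call of the mature adipocyte list was lost (camera adjusted p 0.0513) and that of the p53 list (0.0513). With the mean of a gene's probe sets, the call of the mature adipocyte list was lost (camera adjusted p 0.123). With no filter on dim genes, the call of the mature adipocyte list was lost (camera adjusted p 0.0621) and that of the p53 list (0.0621). With quantile normalization, the call of the ER stress list was lost (camera adjusted p 0.0719), that of the NRF2 list (0.156) and that of the p53 list (0.105), and the oxidative phosphorylation list was called lower (0.00628). Fry did not call the lists of G2 and mitosis (adjusted p 0.283), ER stress (0.118) or matrix (0.140), and it called the RNA interference list (0.00909). Camera also called, with 1 array left out, the S phase list (adjusted p 0.0272 without siLsd1 24 h replicate 2 and 0.0322 without siLsd1 48 h replicate 3) and growth factor list (adjusted p 0.0260 without siLsd1 48 h replicate 3).

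Whether the response to siLsd1 differed between 24 h and 48 h was tested as the difference of both changes. The genes with the smallest p included the chemokine genes Cxcl10, with a difference of 1.32 (SE 0.23, limma adjusted p 0.441, and 0.0175 without siLsd1 48 h replicate 3), and Ccl4, with −2.71 (SE 0.33, adjusted p 0.112, 0.00972 without that array, and 0.00662 with low intensities raised). Others were 0.91 for Nlrc5 (adjusted p 0.441), 0.98 for Syne3 (adjusted p 0.441), 0.63 for Mlkl (adjusted p 0.441) and 0.97 for Aqp1 (adjusted p 0.441). Differences below 0 were −0.64 for Lpar6 (adjusted p 0.441), −0.70 for Ccn1 (adjusted p 0.441), −0.62 for Sat1 (adjusted p 0.446) and −0.81 for Gsta4 (adjusted p 0.446). Among list members, the differences were 1.88 for Cenpf (adjusted p 0.441), 1.28 for Cenpe (adjusted p 0.441), −1.41 for Dusp1 (adjusted p 0.469) and −0.78 for Gadd45g (adjusted p 0.446). limma called 0 of 13644 genes (896 at an unadjusted p under 0.05), and 201 (147 higher and 54 lower) without siLsd1 48 h replicate 3. Camera called 8 of 32 lists, of which the list of G2 and mitosis had the largest median difference, at 1.03. Fry called 0, and 0 were called with an estimated correlation (lowest adjusted p = 0.288 with an estimated correlation). Camera also called, with 1 array left out, the LSD1 complex list (adjusted p 0.0499 without siC 24 h replicate 2, 0.0418 without siC 48 h replicate 2 and 0.00729 without siLsd1 48 h replicate 3), matrix list (adjusted p 0.0390 without siLsd1 48 h replicate 1 and 0.0259 without siLsd1 48 h replicate 2), glycolysis list (adjusted p 0.0390 without siLsd1 48 h replicate 1 and 0.0461 without siLsd1 48 h replicate 2), mature adipocyte list (adjusted p 0.0233 without siC 48 h replicate 1), oxidative metabolism list (adjusted p 0.0499 without siC 24 h replicate 2), NRF2 list (adjusted p 0.0353 without siLsd1 48 h replicate 3), ribosomal list (adjusted p 0.00100 without siLsd1 48 h replicate 3) and skeletal muscle list (adjusted p 0.00915 without siC 48 h replicate 1).

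The comparison of siC at 48 h with siC at 24 h describes the control cells, in which time cannot be told apart from passage. Of 40 genes of G2 and mitosis 39 were called lower, and of 38 S phase genes 35. Camera and fry called both lists, which were not called with an estimated correlation (adjusted p = 0.241 and 0.235 with an estimated correlation). Cdc6, which loads the replicative helicase, fell a floored 8.64-fold, from 159 ± 6.14 (SD, n = 2) to 11.1 ± 2.53 (SD, n = 3; log2 change as measured −3.87, SE 0.39, limma adjusted p 0.000147; Entrez gene 23834). Tk1, thymidine kinase, fell 14.5-fold, from 709.6 ± 173 to 48.5 ± 7.16 (log2 change −3.86, SE 0.30, limma adjusted p 5.35e-05). Tbx6, a transcription factor gene, rose a floored 6.71-fold, from 9.62 ± 2.82 to 124 ± 9.80 (log2 change as measured 3.71, SE 0.36, limma adjusted p 0.000142), and Apoe rose a floored 2.29-fold. Nuf2, Ndc80, Pbk and Bub1 fell 10.4-, 9.67-, 9.19- and 8.94-fold, and Ttk and Esco2 fell a floored 8.003- and 6.46-fold, genes of the kinetochore, of sister chromatid cohesion and of mitotic kinases. Col27a1, Hoxd3os1, Sycp2, Robo3 and Mss51 rose 9.96-, 6.30-, 5.52-, 5.17- and 4.99-fold (log2 change of another probe set of Robo3 at −0.52), and Gdpd3 rose a floored 2.75-fold. Kdm1a had a log2 change of 0.11 (adjusted p 0.666), and Dlk1 fell 1.2-fold (log2 change of another probe set of Dlk1 at 1.23, adjusted p 0.0289).

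limma called 3302 of 13644 genes between the control times, 1640 higher and 1662 lower at 48 h, and 704 of them changed more than 2-fold (260 higher and 444 lower). Centring each array on its median shifted every change between the control times by −0.14 on the log2 scale and took their median from 0.01 to −0.13. Relative to the array median, 3676 genes were called, 1053 higher and 2623 lower. The count was 5510 (2878 higher and 2632 lower) without siLsd1 48 h replicate 3, and 1488 and 1482 without siC 24 h replicate 1 or 2 and 2116 without siC 48 h replicate 2. Of the 116 called genes named here, the calls of 68 held with each array left out, among them Cdc6, Tk1, Tbx6, Apoe, Bub1, Il6, Rsad2 and Sqle. Among the 116, 41 lost the call without either siC 24 h array, 16, 25 and 26 without siC 48 h replicate 1, 2 or 3, 13 without either siLsd1 24 h array, and 3 and 4 without siLsd1 48 h replicate 1 or 2.

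Of the 40 genes of G2 and mitosis tested, 0 rose and 39 fell (0 and 40 adjusted over the list alone). The G2 and mitosis list had a median log2 change of −2.36 (camera adjusted p 1.61e-32, and adjusted p = 0.241 with an estimated correlation). Of the 38 genes of S phase and replication tested, 0 rose and 35 fell (0 and 35 adjusted over the list alone). The S phase list had a median log2 change of −1.34 (camera adjusted p 2.25e-26, and adjusted p = 0.235 with an estimated correlation). Mcm5 and Uhrf1 fell 8.11- and 7.44-fold. Of the 40 interferon response genes tested, 1 rose and 30 fell (3 and 32 adjusted over the list alone). The interferon list had a median log2 change of −0.55 (camera adjusted p 4.00e-17, and adjusted p = 0.163 with an estimated correlation). Cxcl10, Mx1 and Rsad2 fell 5.52-, 4.36- and 3.19-fold and Oasl1 a floored 4.38-fold. Of the 20 cholesterol biosynthesis genes tested, 0 rose and 15 fell (0 and 17 adjusted over the list alone). The cholesterol list had a median log2 change of −0.82 (camera adjusted p 8.92e-09, and adjusted p = 0.526 with an estimated correlation). Idi1, Sqle, Hsd17b7 and Stard4 fell 3.62-, 3.13-, 2.78- and 2.78-fold. Of the 41 ER stress and ATF4 target genes tested, 1 rose and 24 fell (2 and 26 adjusted over the list alone). The ER stress list had a median log2 change of −0.54 (camera adjusted p 8.13e-09, and adjusted p = 0.235 with an estimated correlation). Atf3, Mthfd2, Shmt2 and Chac1 fell 5.82-, 3.73-, 3.11- and 3.03-fold, of which Mthfd2 and Shmt2 encode enzymes of mitochondrial folate metabolism. Of the 32 inflammatory cytokine and NF-kB target genes tested, 0 rose and 9 fell (0 and 9 adjusted over the list alone). The inflammatory list had a median log2 change of −0.20 (camera adjusted p 0.0341, and adjusted p = 0.705 with an estimated correlation). Il6 fell 8.72-fold. Of the 24 contractile and smooth muscle genes tested, 3 rose and 6 fell (3 and 9 adjusted over the list alone). The contractile list had a median log2 change of −0.18 (camera adjusted p 0.0407, and adjusted p = 0.526 with an estimated correlation). Actg2, Tagln and Acta2 fell 3.95-, 3.16- and 2.24-fold (log2 change of another probe set of Acta2 at 0.34). Of the 40 lysosome and autophagy genes tested, 16 rose and 1 fell (16 and 3 adjusted over the list alone). The lysosome list had a median log2 change of 0.22 (camera adjusted p 0.00842, and adjusted p = 0.241 with an estimated correlation). Ctsf and Mcoln1 rose 2.56- and 1.55-fold, and Ctsc fell 2.29-fold. The contractile call was lost at a camera adjusted p of 0.0989 without siC 24 h replicate 1, 0.0679 without siC 48 h replicate 1, 0.0583 without siC 48 h replicate 3 and 0.0605 without siLsd1 48 h replicate 3, and the inflammatory call at 0.0911 without siC 24 h replicate 1 and 0.0620 without siC 48 h replicate 3. With camera run without an intensity trend, the call of the contractile list was lost (camera adjusted p 0.0618) and that of the inflammatory list (0.0509). With the mean of a gene's probe sets, the call of the contractile list was lost (camera adjusted p 0.185) and the TGF-beta and BMP list was called lower (0.00486). Fry did not call the inflammatory list (adjusted p 0.0728), and it called the TGF-beta and BMP (0.0281), germline (0.0358) and NRF2 lists (0.0422). With no filter on dim genes, the call of the contractile list was lost (camera adjusted p 0.0719). With quantile normalization, the call of the contractile list was lost (camera adjusted p 0.141) and that of the inflammatory list (0.102). Camera also called, with 1 array left out, the glycolysis list (adjusted p 0.0361 without siLsd1 48 h replicate 3).

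Camera with an estimated correlation, like fry not rerun without siLsd1 48 h replicate 3, called 0 of 32 lists in each comparison. At the preset correlation it called 9 lists at 24 h, 5 at 48 h, 8 for the mean of both times, 8 for the difference between the times and 8 between the control times, against 12, 8, 10, 12 and 9 at an unadjusted p under 0.05, and fry called 6, 5, 6, 0 and 10, not all of them among the lists camera called.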

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

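The tests of siLsd1 48 h replicate 3 as the source of the G2 and mitosis difference, of leukocytes and of array scaling for the interferon genes were chosen after the result was seen.

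The effects of siLsd1 at 24 h and 48 h differed by camera for 8 lists, of which fry called 0 and 0 held with an estimated correlation (lowest adjusted p = 0.288 with an estimated correlation). The median log2 change at 48 h minus that at 24 h was 1.03 for G2 and mitosis genes (camera adjusted p 1.18e-32), 0.40 for S phase genes (camera adjusted p 1.53e-11), 0.27 for ER stress and ATF4 targets (camera adjusted p 1.18e-05), 0.20 for cholesterol biosynthesis genes (camera adjusted p 0.0208) and 0.19 for interferon response genes (camera adjusted p 1.41e-06). It was −0.25 for inflammatory genes (camera adjusted p 3.73e-05), −0.21 for growth factor and immediate early genes (camera adjusted p 0.00386) and −0.056 for p53 targets (camera adjusted p 0.0481). On siLsd1 48 h replicate 3 the S phase list lay at 0.42 against 0.00 and −0.07 on its replicates, and the cholesterol list at −0.48 against 0.28 and 0.15; without it these 2 differences were 0.32 and 0.42, and those of the ER stress and growth factor lists were 0.17 and −0.12. limma called 0 single genes (896 at an unadjusted p under 0.05). With 1 array left out, the p53 call was lost at adjusted p of 0.134 without siC 24 h replicate 1, 0.0547 without siC 48 h replicate 2, 0.0851 without siC 48 h replicate 3, 0.133 without siLsd1 24 h replicate 1, 0.139 without siLsd1 48 h replicate 2 and 0.0868 without siLsd1 48 h replicate 3. The cholesterol call was lost at 0.143 without siC 24 h replicate 1, 0.0851 without siC 48 h replicate 3, 0.201 without siLsd1 24 h replicate 1, 0.293 without siLsd1 48 h replicate 1 and 0.162 without siLsd1 48 h replicate 2. The calls of the other 6 lists held in each of the 10 fits without 1 array, but with the mean of a gene's probe sets the inflammatory and growth factor calls were lost (0.0795 each), as was the cholesterol call (0.359). The p53 call was also lost with no filter on dim genes (0.133) and with camera without an intensity trend (0.0711).

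The list of G2 and mitosis genes was called lower with siLsd1 at 24 h by camera and not at 48 h; the 24 h call was lost by fry (adjusted p 0.0998) and with an estimated correlation (adjusted p = 0.596 with an estimated correlation). Without siLsd1 48 h replicate 3 the difference between the times had a camera adjusted p of 7.42e-23, which argues against that array as the sole source, and with any other array left out the highest was 2.14e-24, which argues against any 1 of those. Fry gave an adjusted p of 0.209 and the adjusted p was 0.288 with an estimated correlation, so a spread between cultures that these genes share stays open. In control cells the same list fell between the times by a median of −2.36, and no biological explanation was tested. Passage differs with time in the same way and stays open too.

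The interferon response list was called higher with siLsd1 at both times by camera and fry, though not with an estimated correlation (adjusted p = 0.10 at 24 h and 0.0692 at 48 h with an estimated correlation). The samples were of 3T3-L1, a fibroblast line, and no label names leukocytes. The 15 leukocyte markers tested, of 24 in the list, had a median log2 change of 0.0424 at 48 h, and limma called 0 of them at either time. Only Cd14 and Lyz1 reached 304 intensity units in control cells at 48 h, so the markers alone cannot decide whether leukocytes were present. Mpeg1 and Ctss, which macrophages express, rose 5.67- and 2.59-fold at 48 h, but they are not in that list and were taken from among the genes that rose. Array scaling is argued against, since after quantile normalization the higher of the camera adjusted p at both times was 4.27e-15. A response to the siRNA duplex cannot be told apart from loss of LSD1, because 1 siRNA against LSD1 was used; the 48 h array with the lowest Kdm1a, siLsd1 48 h replicate 3, had a list median that differed from the mean of its replicates by −0.142. Loss of LSD1 as the source was not separated from these.

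Outside the comparisons, 4779 of the 10092 probe sets without a single gene symbol passed the filter on dim probe sets. Tested as in the comparisons, 46 of them were called with siLsd1 at 24 h, 110 at 48 h and 998 between the control times (776 higher and 222 lower).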

How the results depend on the processing

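Averaging siLsd1 48 h replicates 1 and 2, adding 16 to the intensity, raising intensities under 18.4 to that level and camera without an intensity trend were chosen after the result was seen. Over 562 named results, 13146 comparisons with alternatives left 11086 on the same side of the threshold in the same direction, 1899 lost the call, 150 gained it and 11 changed sign. Where a cause is not named here, the cause was not tested. Low signal limits the precision of dim genes: the median residual SD was 0.316 at a log2 intensity of 4 to 6 and 0.111 at 10 to 12.

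Counts of called genes (736 at 24 h, 1728 at 48 h, 3250 for the mean of both times, 0 for the difference and 3302 between control times) moved as follows. Array weights, which gave siLsd1 48 h replicate 3 the weight 0.0948, called 3571, 4922, 5602, 434 and 6192. Requiring a 1.5-fold change left 438, 728, 857 and 1785, with the difference at 0. The mean of a gene's probe sets gave 427 at 24 h, 948 at 48 h and 2134 for the mean. Without an intensity trend the counts were 402 at 24 h, 1006 at 48 h and 1 for the difference. The arrays compared alone gave 3183 at 24 h and 250 at 48 h. The unequal-variance test per gene called 1 at 24 h, 1 at 48 h and 817 between control times; it and the fit of the arrays compared alone were not run for the mean and the difference. Adding 16 to the intensity gave 3 for the difference, and so did raising low intensities. With 1 array left out the counts ranged from 30 to 3478 at 24 h, 382 to 2473 at 48 h, 1346 to 4617 for the mean, 0 to 201 for the difference and 1482 to 5510 between control times; such fits assume that a lone array varies like the other groups. Each of these counts at its highest came without siLsd1 48 h replicate 3.

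As a replicate block, the replicate number gave 149 at 24 h, 665 at 48 h, 2081 for the mean, 0 for the difference and 547 between control times, with 3 residual degrees of freedom. A block by sample code gave 1467 at 24 h and 59 for the difference, with 1. The numbers do not pair the samples: the deviations of same-numbered arrays correlated at −0.19 to 0.05, against up to 0.15 for other pairs, and not every array correlated best with its own number.

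Kdm1a kept its log2 change of −0.69 at 24 h but missed the threshold with all probe sets tested (adjusted p 0.0693), no filter (0.0576), no trend (0.0903) and the block (0.107), and at 48 h, at −0.55, with no trend (0.0649), the arrays compared alone (0.104) and the block (0.0664). With the block by sample code its 48 h change was −0.33 (adjusted p 0.00647). With 1 array left out the change ranged from −0.72 to −0.66 at 24 h (adjusted p 4.81e-05 to 0.252) and from −0.65 to −0.35 at 48 h (0.00277 to 0.115).

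The correlation of 0.617 became 0.510 with all probe sets, 0.538 with array weights, 0.678 with 16 added, 0.645 with low intensities raised, 0.759 without the lowest 50% of genes, 0.526 with the mean of probe sets, 0.324 with no filter, 0.489 with the block by code, and 0.560 to 0.607 with 1 array left out.

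With an estimated correlation camera called 0 lists in each comparison, and for the difference fry called 0 and the mean of probe sets 5. The replicate block ended the inflammatory call between control times (0.329) and the p53 call for the difference (0.0724), and no other list call. It added calls of the pro-adipogenic list at 48 h (0.0249) and of the TGF-beta and BMP (0.0326) and matrix lists (0.0110) between control times. With 1 array left out the lists called ranged from 8 to 11 at 24 h, 5 to 7 at 48 h, 5 to 10 for the mean, 6 to 10 for the difference and 6 to 8 between control times.

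With the mean of a gene's probe sets, which brings in a gene's other probe sets, 11 changes turned sign: Acta2 to 0.022, Dlk1 to 0.48 and Rfng to −0.10 between control times, Acta2 to −0.060, Ddit3 to −0.10, Des to −0.21 and Fto to 0.16 at 48 h, Inhba to −0.34, Pola1 to 0.30 and Setd7 to −0.0077 at 24 h, and Inhba to −0.087 for the mean.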

Other observations

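Among the results below, the tests of a wrong label and of a less advanced culture for siLsd1 48 h replicate 3 were chosen after the result was seen.

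For the mean of both times, members of lists that camera did not call were called by limma. Of the 36 pro-adipogenic regulators, 3 rose and 12 fell (3 and 13 adjusted over the list alone), with a camera adjusted p of 0.105. The list median was −0.52 on siLsd1 48 h replicate 3 against −0.10 and −0.17 on its replicates. Ebf2, Igf1, Ebf3 and Zfp467 fell 2.35-, 1.97-, 1.91- and 1.47-fold, of which the Ebf genes and Zfp467 encode adipogenic transcription factors and Igf1 a growth factor. Of 28 genes of LSD1 complexes, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with a camera adjusted p of 0.316; besides Kdm1a, Phf21a, Zmym3 and Chd3 fell 1.65-, 1.62- and 1.37-fold. Of 35 Wnt genes, 5 rose and 6 fell (camera adjusted p 0.797), among them Tcf7l1, which fell 1.85-fold, and Myc and Ccn4, which rose 1.77- and 1.64-fold. Of 15 genes of the RNA interference machinery, 1 rose and 6 fell (camera adjusted p 0.142); Prkra and Tnrc6b fell 1.63- and 1.51-fold and Tarbp2 rose 1.28-fold.

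Between the control times, limma also called members of lists that camera did not call. Of 39 TGF-beta and BMP genes, 6 rose and 10 fell (camera adjusted p 0.183); Id4, Id3 and Id2 fell 4.49-, 3.09- and 2.99-fold (log2 change of another probe set of Id2 at 0.36) and Bmp1 rose 2.25-fold. Of 53 matrix genes, 6 rose and 11 fell (camera adjusted p 0.438), with Tnc and Ccn2 falling 4.93- and 3.84-fold. Of 34 mature adipocyte markers, 5 rose and 7 fell (camera adjusted p 0.955); Plin4 rose 3.23-fold and Cd24a fell 1.56-fold. Of 44 histone methylation enzymes, 9 rose and 7 fell (camera adjusted p 0.636); Setdb2 and Ezh2 fell 3.13- and 2.32-fold, and Kdm7a and Kmt2e rose 1.84- and 1.60-fold. Of 23 glycolysis genes, 2 rose and 6 fell (camera adjusted p 0.0969); Hk2 and Pkm fell 2.98- and 1.83-fold and Eno2 rose 1.83-fold. Time and passage differ together in this comparison.

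SiLsd1 48 h replicate 3 differed from its replicates by an SD of 0.441 and 0.439 on the log2 scale, against 0.0892 to 0.205 for other pairs of a group. Its SD from the siLsd1 24 h arrays was 0.361 and 0.353, also beyond 0.205 but smaller than that from its own replicates. By that bound the array matched neither group, so a siLsd1 24 h sample under the wrong label stays open. Array scaling is argued against, because after quantile normalization the nearer replicate still lay at 0.430 against 0.207 for other pairs. On 77.9% of the 3302 genes called between the control times the array deviated against the control change, so a culture less far along that change may be part of the difference, but the share does not decide it. On 71.6% of the 736 genes called at 24 h it deviated in the direction of the siLsd1 change at 24 h, and its Kdm1a was the lowest of the 48 h arrays, so a deeper knockdown stays open as well. No label gives a batch for this array.

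For the mean of both times, 1 of 60 splits within the times, the real one, gave as many called genes (3250, highest other 1). Splits mixing the siRNAs widen the spread, so chance stays open. At 48 h the 6 arrays allow 10 splits, too few for a share under 0.05; the real count was 1728 and the highest other 0.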
